A study of Mus musculus with 8 samples.

How the data were processed

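Chromatin immunoprecipitation with sequencing was applied to kidney cortex of 2-month-old mice whose genotype carries loxP-flanked Mta2 alleles, per the labels. The labels name 8 libraries in 4 groups, with 2 biological replicates each: antibodies against Mta2, Mbd3 and Zbtb7a, and Input chromatin. Mta2 and Mbd3 are subunits of the nucleosome remodelling and deacetylase (NuRD) complex, and Zbtb7a is a zinc finger transcription factor. Per the labels' protocols, tissue was crosslinked with 2 mM disuccinimidyl glutarate and then with 1% formaldehyde, chromatin was sheared to fragments of 100 to 1000 bp, and libraries were sequenced on an Illumina NovaSeq to a stated depth of 100 M paired-end reads. Per the submitters' processing notes, Bowtie2, deepTools, MACS2, bedtools and the mm10 genome build were used, and their versions and settings are not given in the sources used here.

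The values analysed were 3 peak lists, 1 per factor. Column names are absent from the lists, and their layout is that of the narrowPeak format. Each line holds an interval, the fold enrichment at the summit, a ratio of signal over background that the authors' peak caller computed, the deposited −log10 q value, and the deposited offset of the summit from the interval's start. Each list stands for both mice of its group, and whether reads or peaks of the mice were combined is not stated in the labels. The lists therefore carry no value per mouse, so no SD or n accompanies a value, and the tests run over positions or genes and not over animals. Each fold is the authors' own value for that peak. Fold and −log10 q were used only to describe, rank and filter peaks within a list, because lists can differ in antibody and depth. The read depth of each library was not analysed here, and a region without a peak was below the authors' threshold at this depth and cannot be read as unbound. How the Input libraries entered peak calling is not stated, and Input was not analysed separately.

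Intervals on autosomes and chromosome X formed the main data, and no line shared its interval with another. Overlap meant at least 1 shared bp. Chance overlap came from 1000 circular shifts of one list within the span that peaks cover on each chromosome, with one-sided p-values. Peaks of all lists were merged into union regions for counts of sharing. For strength, each list was divided into 10 equal parts by fold. For agreement at the top, equally long lists of the highest −log10 q were compared, with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only, and exact McNemar tests, two-sided.

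Gene positions came from RefSeq for GRCm38.p6, which shares its coordinates with mm10. The table used here gives the start and end of each gene and neither strand nor transcripts. The planned windows around transcription start sites were therefore replaced by windows of 1 kb around both ends of each of 21631 protein-coding genes on autosomes and X, so an occupied end can be the 5′ or the 3′ end. A peak close to ends of neighbouring genes counts for each of them, and an internal promoter counts for none. Whether the ends come from predicted transcripts is not given, so a gene's main promoter can lie inside its span, and a gene without a summit near an end can hold summits inside it. Planned motif counts, a background matched on CpG content and windows at the 5′ end alone needed sequence or strand and were not run. Occupancy was compared between 26 gene lists and all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 78 tests at a threshold of 0.05. That test takes genes as independent, so its p-values can be too small where members of a list lie side by side. Differences between factors within a list used the exact McNemar test with the same adjustment. Of 479 listed symbols, 478 were current and 1 was matched by a synonym to a gene already listed. Some lists share members, among them 14 of the 36 FSGS genes with other lists.

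Gene lists, the main tests, the alternatives below and the rule for named genes were fixed before the data were examined. The lengths of top lists other than 10000, the McNemar tests, the gene families and the counts of summits around genes were added after. The rule named every NuRD subunit and Zbtb7a, the 3 members of each list with the highest Mta2 fold at a gene end and up to 2 members, first in the alphabet, without a peak at an end in any list. It also named the 5 genes of highest fold per list, the 5 strongest intervals per list and the 3 strongest that overlap neither other list. Some genes that the rule named are not reported here. The lists cover NuRD subunits, cell types of the kidney, genes of focal segmental glomerulosclerosis (FSGS) and nephrotic syndrome, metabolism, cell cycle and arrest, fibrosis, globins, zinc finger partners of NuRD, ribosomal proteins, immune cells and 4 tissues outside the kidney.

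Alternatives included a −log10 q of at least 10, a fold of at least 5, the 10000 top peaks, windows of 0.5 kb and 3 kb, reciprocal overlap of 50%, summits within 100 bp, shifts of 50 kb to 1 Mb, random placement with bedtools and a background without olfactory and vomeronasal receptor genes. Alternatives used 200 shifts or 100 random placements. The overlap test was tested on simulated lists of the same size. For Mta2 peaks against a simulated Zbtb7a list, over 149855 peaks, a planted share of 30.0% came back as 28.9% and of 70.0% as 69.1%, and with none planted the overlap was 1.01 times that of shifts. The Fisher test was run on 200 simulated lists of 25 genes against a background of 21631 genes, with each gene drawn independently of its neighbours. It called 5.5% of lists with the background's share at an unadjusted threshold of 0.05, and 96.5% of those in which 95% of genes were occupied. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.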

Results

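Binding of Mta2, Mbd3 and Zbtb7a was mapped in kidney cortex of 2-month-old mice. The study concerns FSGS, a scarring disease of the glomerulus, after loss of Mta2 from nephron progenitors, and these libraries asked where the NuRD subunits and Zbtb7a sit in the adult cortex. There were 2 mice per group, and the sample titles carry the same pair of numbers in every group, so the factors appear to have been mapped in the same animals. As 1 peak list per factor stands for both, spread between mice could not be measured. The read depth of each library was not analysed here. The lists held 149855 peaks for Mta2, 134248 for Mbd3 and 124616 for Zbtb7a on autosomes and X, covering 94.3, 78.1 and 68.5 Mb. Median peak widths were 450, 422 and 393 bp, and every peak had a −log10 q of at least 1.3.

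The 5 strongest Zbtb7a peaks by fold lay within 1 kb of a gene end. Of the 100 Zbtb7a peaks of highest −log10 q, 57.0% did so. The highest fold in that list, 465, belonged to a peak 787 bp from the upper end of Ski, a repressor of TGF-beta signalling (mm10, chromosome 4, 155221458 to 155224071). The next were peaks at Yipf6 (fold 362, chromosome X, 98936649 to 98938486), at Tmem80 within Deaf1 (fold 346, chromosome 7, 141326584 to 141328852), at Acin1 and the adjoining 1700123O20Rik (fold 299, chromosome 14, 54685660 to 54687426) and at Tada1, a subunit of the SAGA acetyltransferase complex (fold 282, chromosome 1, 166378497 to 166380262). Each of these peaks overlapped a Mta2 and a Mbd3 peak. At Yipf6 the Mta2 and Mbd3 summits lay beyond 1 kb of the gene's ends.

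The strongest Mta2 peaks were inside Mllt10 (fold 174, chromosome 2, 18055963 to 18058350), inside Mpp7 (fold 119, chromosome 18, 7608644 to 7609755), at the end of Fam120a (fold 113, chromosome 13, 48966767 to 48968975), at the end of Prpf40b (fold 94.6, chromosome 15, 99294552 to 99295975) and 18025 bp from Armc12 (fold 89.7, chromosome 17, 28512092 to 28514911). The Armc12 interval was also among the 5 strongest of Mbd3, at fold 97.2. The other strong Mbd3 peaks were 8455 bp from Tob2 (fold 97.9, chromosome 15, 81838454 to 81840539) and inside Tpcn2 (fold 97.7), Chd9 (fold 87.7) and Tns1 (fold 86.5). Genes with the highest Mta2 fold at an end also included Sp1, a zinc finger activator that binds GC boxes, at 84.2, Mindy2 at 84.1 and E2f5, an E2F family member, at 81.1. For Mbd3 they were E2f5 at 82.65, Mindy2 at 82.3, Zfat at 74.9, Pck1, the rate-limiting enzyme of gluconeogenesis, at 74.8 and Proc at 70.4.

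Peaks that overlapped neither other list were weaker. The strongest of Mta2 lay 95 bp from an end of Syt10 (fold 8.37), 304 bp from Cbln2 (fold 7.93) and 5166 bp from Hspa8 (fold 7.51). For Mbd3 they lay 95537 bp from Ice1 (fold 9.97), inside Rbms3 (fold 9.67) and inside Slk (fold 8.26). For Zbtb7a they had folds of 21.0, 16.7 and 14.65 and widths of 166, 161 and 165 bp. Their nearest protein-coding genes were Rpia, Tox3 and Gm21129, with ends 1249235, 492007 and 10283 bp away. None of these peaks lay inside a protein-coding gene, and other genes were not examined.

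The first comparison asked how far the NuRD subunits and Zbtb7a occupy the same places. Of Mbd3 peaks, 92.8% overlapped a Mta2 peak and 80.6% a Zbtb7a peak. Of Zbtb7a peaks, 92.0% overlapped Mta2 and 88.8% Mbd3. Of the longer Mta2 list, 80.5% overlapped Mbd3 and 72.4% Zbtb7a. Circular shifts gave 5.56% to 7.19% on average, so that overlap was 12.6 to 14.7 times that of shifts, and in all 6 comparisons p was 0.001, the smallest that 1000 shifts can give (one-sided). Shifts place peaks anywhere in the span, so these p-values cannot set the overlap apart from signal that any antibody may collect at open chromatin. The 3 lists merged into 164813 regions, of which 101152 (61.4%) held a peak of all 3 factors, against 940.5 regions on average with shifts. Mta2 alone held 23165 regions, Mta2 with Mbd3 17832, Zbtb7a alone 7203, Mbd3 alone 6889, Mta2 with Zbtb7a 5950 and Mbd3 with Zbtb7a 2622. These shares depend on the lengths of the lists.

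Sharing rose with peak strength. In the weakest 10% by fold, 17.8% of Mta2 peaks (95% interval 17.2 to 18.4), 30.7% of Mbd3 peaks (29.9 to 31.5) and 49.99% of Zbtb7a peaks (49.1 to 50.9) overlapped both other lists. In the strongest 10% these shares were 99.97%, 100.0% and 99.99%. Peaks in all 3 lists had a median fold of 7.66 in the Mta2 list, against 2.92 for Mta2 peaks that overlapped neither other list. The corresponding medians were 6.34 and 2.68 for Mbd3 and 5.78 and 2.78 for Zbtb7a.

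**Figure D1:**
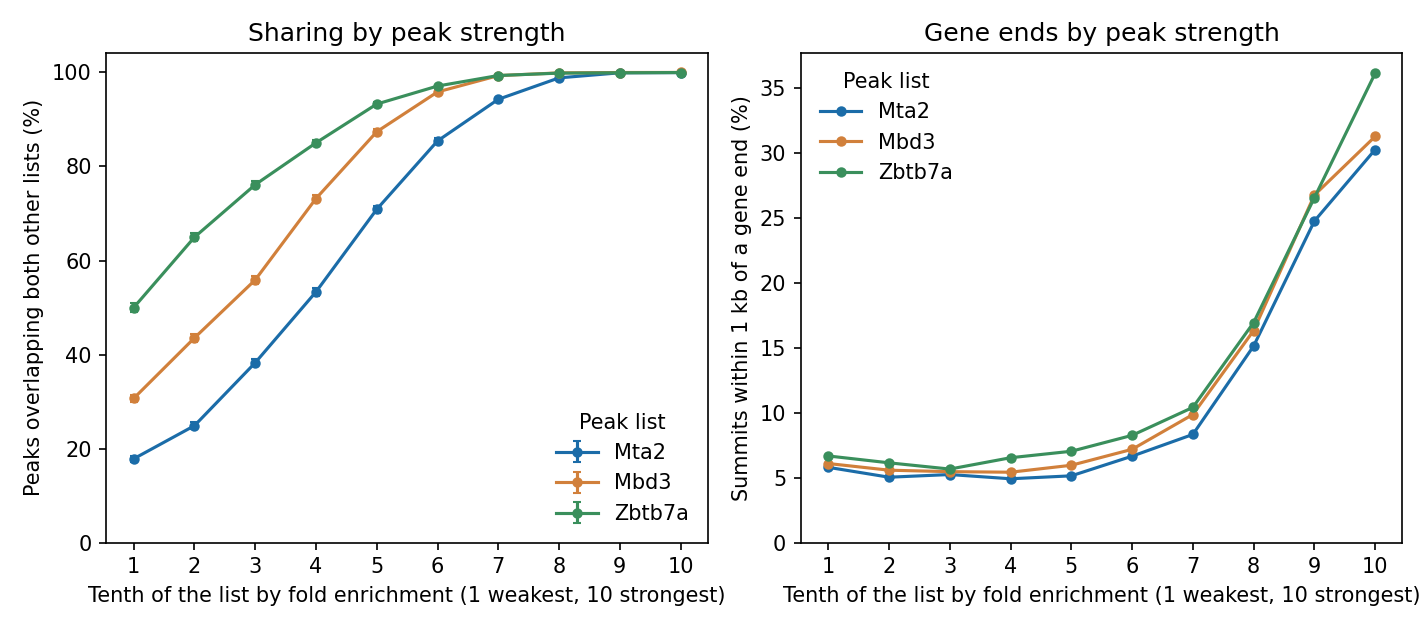
Left, share of peaks overlapping both other lists (%) by fold enrichment within each list in 10 equal parts, with exact 95% binomial intervals; right, share of summits within 1 kb of a protein-coding gene end (%) by the same parts. Sharing went from 17.8% to 99.97% for Mta2, and the share near gene ends from 5.80% to 30.3%.

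Among equally long lists of top peaks, Mta2 shared more with its NuRD partner Mbd3 than with Zbtb7a. Of the 500 Mta2 peaks of highest −log10 q, 69.4% (95% interval 65.15 to 73.41) overlapped one of the 500 top Mbd3 peaks and 38.8% (34.5 to 43.2) one of the 500 top Zbtb7a peaks. There were 188 of these Mta2 peaks in the Mbd3 top list alone and 35 in the Zbtb7a top list alone (exact McNemar p = 1.63e-26). With 10000 top peaks the shares were 85.7% and 76.8%, with 1444 and 547 peaks in a single list (exact McNemar p = 6.53e-93). The length of 500 peaks and this test were chosen after the lists were seen. The test counts peaks and not mice, so its p-values do not cover differences between animals, antibodies or read depths. Whether a difference in antibody or depth lowered the sharing with Zbtb7a was not tested. The 100 top peaks included 7 of Mta2, 7 of Mbd3 and 3 of Zbtb7a with a fold under 3 and a −log10 q above 100.

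**Figure D2:**
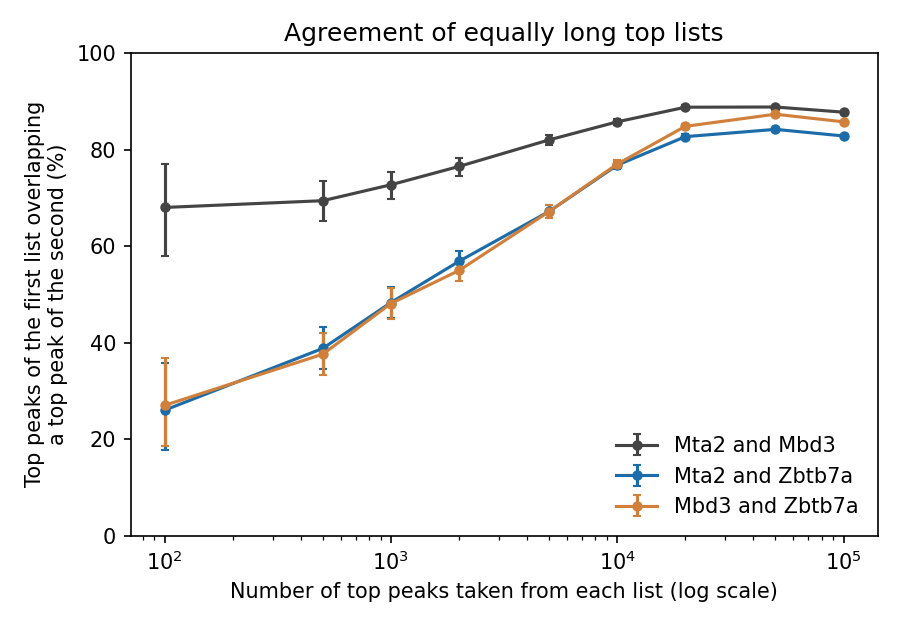
Share of the top peaks of the first list that overlap a top peak of the second (%), by the number of top peaks taken from each list on a log axis; bars are exact 95% binomial intervals. At 500 peaks Mta2 and Mbd3 share 69.4%, and Mta2 and Zbtb7a 38.8%.

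The second comparison placed the peaks relative to genes. Within 1 kb of a protein-coding gene end lay 11.1% of Mta2 summits, 12.0% of Mbd3 summits and 13.05% of Zbtb7a summits, which was 3.51, 3.78 and 4.09 times the share with shifts (permutation p = 0.001 for each, one-sided, the smallest that 1000 shifts can give). A further 51.9%, 51.9% and 51.8% lay inside a gene away from its ends, and 36.95%, 36.13% and 35.16% outside genes. In the strongest 10% the share at gene ends was 30.3% for Mta2, 31.3% for Mbd3 and 36.2% for Zbtb7a. A summit lay at an end of 14539 genes (67.2%) for Mta2, 14165 (65.5%) for Mbd3 and 14188 (65.6%) for Zbtb7a. All 3 factors were at 13512 genes (62.5%) and none at 6550 (30.3%). A gene counts for all 3 even where they lie at opposite ends of it. Mta2 was alone at 399 genes, Zbtb7a at 260 and Mbd3 at 123.

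The third comparison asked which gene groups carried the factors at their ends. The chromatin came from cortex tissue, so a peak at a gene of one cell type cannot be assigned to that cell type. Likewise, a low share for such a list does not show that the factors are absent in those cells. All 15 NuRD subunit genes did so for all 3 factors (adjusted exact p = 0.0117 for Mta2 and 0.00851 for Mbd3 and for Zbtb7a, Fisher's exact test). These calls were lost for all 3 factors with windows of 0.5 kb and for Mta2 with 3 kb. At the Mbd3 gene the strongest Mta2 and Zbtb7a peaks near an end lay at its lower end and that of Mbd3 at its upper end. The Zbtb7a peak at Mta2 itself was among the strongest of its list (fold 145, the 99.9th percentile of occupied genes, chromosome 19, 8941469 to 8942797). Its summit lay 16 bp from the lower end of Mta2, and the interval also spans the upper end of the neighbouring Eml3 at 8941582. Mta2 and Mbd3 peaks lay at the same place with folds of 21.3 and 17.2, the 74.6th and 64.5th percentiles of occupied genes for those factors. The histone deacetylase gene Hdac1 and the subunit gene Cdk2ap1 carried Zbtb7a folds of 49.1 and 45.8, at percentiles 97.1 and 96.2 of occupied genes. Gatad2a, Gatad2b, Mbd2, Mbd3, Mta1, Mta3, Rbbp4, Rbbp7 and Hdac2 had Mta2 folds from 10.7 at Hdac2 to 29.05 at Mbd2. Among the remodelling ATPases, Chd4 had a Mta2 fold of 14.9, Chd3 6.43 and Chd5, mainly known from neurons, 5.945. At the Zbtb7a gene the highest Zbtb7a fold near an end was 4.54, 514 bp from the upper end and at percentile 10.9 of occupied genes. Inside the gene's span lay 9 Zbtb7a summits.

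**Figure D3:**
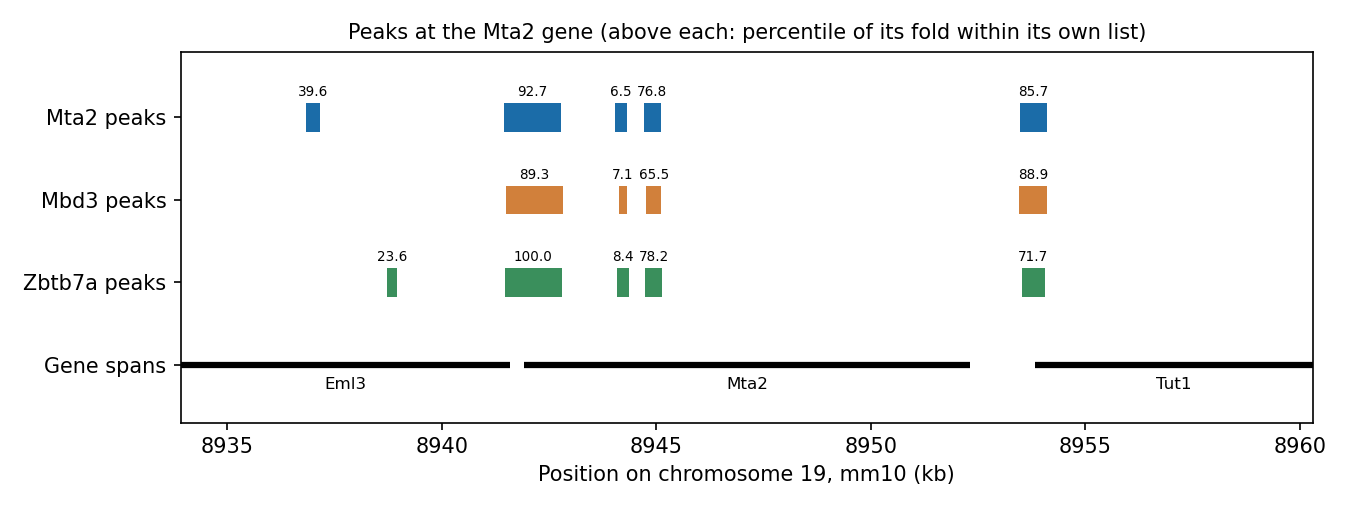
Map of chromosome 19 around Mta2 (position in kb, mm10) with peaks of each list as boxes, the percentile of each peak's fold within its own list above them, and spans of protein-coding genes below. The Zbtb7a peak between Eml3 and Mta2 has a fold of 145, at the 99.99th percentile of all Zbtb7a peaks.

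Of 30 proximal tubule genes, 27 carried Mta2 (90.0%, against 67.2% of other genes, adjusted exact p = 0.0153), 29 Mbd3 and 29 Zbtb7a (96.7%, adjusted exact p = 0.000668 for both). Mta2 folds there were highest at Pck1 (67.4), at the water channel gene Aqp1 (41.6) and at the amino acid transporter gene Slc6a19 (37.9). Slc4a4, the basolateral bicarbonate transporter, had no peak at its ends but 62 Mta2 summits inside its span. Podocyte genes passed for Mbd3 and Zbtb7a (25 of 28 each, 89.3%, adjusted exact p = 0.0186) and missed the threshold for Mta2 (24 of 28, 85.7%, adjusted exact p = 0.0703). They included the laminin gene Lamb2 (Mta2 fold 59.97), Podxl (33.7) and Col4a4 (32.2), while Magi2 and Trpc6 had no peak at an end. At Lamb2 the strongest Mta2 and Mbd3 peaks near an end lay at the upper end and that of Zbtb7a at the lower. The podocyte call for Mbd3 was lost with a −log10 q of at least 10.

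Of 36 FSGS and nephrotic syndrome genes, 14 of them also in other lists, 32 carried Mta2 (88.9%, adjusted exact p = 0.0117), 32 Mbd3 (adjusted exact p = 0.00882) and 33 Zbtb7a (91.7%, adjusted exact p = 0.00363). Lamb2, the lipid enzyme gene Sgpl1 (Mta2 fold 42.8) and the formin gene Inf2 (31.8) led for Mta2, and Magi2, Trpc6 and Pdss2 had no summit near an end. Inside their spans Magi2 held 31 Mta2 summits, Pdss2 32 and Trpc6 0. Nphs1, the slit diaphragm gene, was named after its values were seen and was the 1 FSGS gene with some but not all factors at an end. It carried Zbtb7a there, without Mta2 or Mbd3. The other nephron lists were small. Loop of Henle genes passed for Mbd3 alone (10 of 10, adjusted exact p = 0.0377, with Mta2 at 10 and Zbtb7a at 9), among them Umod, Cldn10 and, without Zbtb7a at an end, Enox1. Parietal epithelium genes (10, 9 and 9 of 10 for Mta2, Mbd3 and Zbtb7a, with Ncam1, Ly6a and Pax2), distal convoluted and connecting tubule genes (10 of 12 each, with Klhl3, Wnk4 and Wnk1 but not Slc8a1 or Trpm6, which held 27 and 12 Mta2 summits inside their spans), collecting duct genes (15 of 18 each, with Scnn1a, Aqp4 and Tfcp2l1 but not Elf5 or Foxi1) and nephron progenitor genes (19, 18 and 18 of 22, with Lhx1, Wnt4 and Crym but not Eya1 or Sall1) did not pass. Inside their spans Eya1 held 5 Mta2 summits, Sall1 8, Elf5 5 and Foxi1 0. With windows of 3 kb, nephron progenitor genes passed as more often occupied for all 3 factors.

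All 29 TCA cycle and oxidative phosphorylation genes carried all 3 factors (adjusted exact p = 0.000202 for Mta2 and 0.000153 for the others), with Mta2 folds of 28.0 at Sdhb, 27.0 at Cox4i1 and 25.8 at Mdh2. Of 26 fatty acid oxidation and peroxisome genes, 24 carried each factor (92.3%, adjusted exact p = 0.0145 for Mta2 and 0.0103 for the others). Ppara, the transcription factor that drives this pathway, had a Mta2 fold of 43.9 and a Zbtb7a fold of 120.0 (99.9th percentile), and the dehydrogenase genes Acadl and Acadm had Mta2 folds of 37.2 and 30.6. Cpt1a and Fabp1 had no peak at an end, with 15 and 0 Mta2 summits inside their spans. Lipid and cholesterol synthesis genes passed for Mta2 and Mbd3 (20 of 22 each, adjusted exact p = 0.0392 and 0.0258) and not for Zbtb7a (19 of 22, adjusted exact p = 0.0703), with the highest Mta2 folds at Sqle, Dhcr7 and Fasn and with Elovl6 and Fdft1 without a summit near an end but with 22 and 10 Mta2 summits inside their spans. Glycolysis genes passed for Mbd3 (18 of 20, adjusted exact p = 0.0377), with 18 for Mta2 and 17 for Zbtb7a, and the highest Mta2 folds at Gpi1, Pfkm and Hk2. Hk1 and Ldha had no summit near an end but 24 and 3 Mta2 summits inside their spans. The lipid synthesis calls were lost with windows of 0.5 kb, and the glycolysis call with 0.5 kb and 3 kb.

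Ribosomal protein genes carried Mta2 and Zbtb7a at 30 of 30 and Mbd3 at 29 (adjusted exact p = 0.000202, 0.000153 and 0.000668), with Rpl3 (Mta2 fold 40.9), Rpl27 (28.9) and Rps19 (24.1) highest. Proliferation genes carried Mta2 and Mbd3 at 19 of 20 (adjusted exact p = 0.0164 and 0.0116) and Zbtb7a at 20 (adjusted exact p = 0.0033), with the highest Mta2 folds at Ccne1, Birc5 and E2f1. Genes of p53, senescence and arrest passed for Zbtb7a (15 of 16, adjusted exact p = 0.0344) with Mta2 and Mbd3 at 13. Sesn1, a stress-induced p53 target, had a Zbtb7a fold of 101 (99.8th percentile), Cdkn1b had a Mta2 fold of 36.15, and Cdkn1a had no peak at an end. Inside its span Cdkn1a held 1 Mta2, 2 Mbd3 and 2 Zbtb7a summits. Fibrosis and TGF-beta genes passed for Mbd3 (18 of 19, adjusted exact p = 0.0156), with Mta2 at 17 and Zbtb7a at 16, and the highest Mta2 folds at Smad3 (49.1), Smad2 (34.8) and Ccn2 (31.65), while Tgfb2 had 8 Mta2 summits inside its span and none near an end. That call was lost with windows of 0.5 kb and 3 kb and with a −log10 q of at least 10. The calls for proliferation genes with Mta2 and for p53 genes with Zbtb7a were lost with 0.5 kb.

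Among the other cells of the cortex, endothelial genes passed for Zbtb7a (14 of 14, adjusted exact p = 0.0116), with Mta2 and Mbd3 at 13 and the highest Mta2 folds at Kdr, Eng and Plvap. That call was lost with a −log10 q of at least 10 and with windows of 3 kb. Mesangial, stromal and smooth muscle genes did not pass (13, 12 and 14 of 16 for Mta2, Mbd3 and Zbtb7a, with Pdgfrb, Vim and, without Mbd3 at an end, Foxd1 but not Acta2). Acta2 held 2 Mta2 summits inside its span. Immune genes were occupied less often than other genes by Mta2 (4 of 16, adjusted exact p = 0.00363) and Mbd3 (3 of 16, adjusted exact p = 0.0015), and Zbtb7a at 6 of 16 missed the threshold (adjusted exact p = 0.0552). Cd3e, Cd4 and Lyz2 had a Mta2 peak, the last at fold 3.34, while Adgre1 had no peak of any factor. The Mta2 call was lost with windows of 3 kb, and Zbtb7a passed, as less often, with windows of 0.5 kb, with a −log10 q of at least 10 and without olfactory and vomeronasal receptor genes.

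Globin, liver and germ cell genes were occupied less often than other genes by all 3 factors with windows of 1 kb. With windows of 3 kb the hepatocyte calls were lost for all 3 factors and the globin and germ cell calls for Mta2, and with 0.5 kb the hepatocyte calls for Mta2 and Mbd3. Of 12 globin locus genes and globin regulators, 2 carried each factor (16.7%, adjusted exact p = 0.0033 for Mta2 and 0.00363 for the others), the regulator genes Bcl11a and Zbtb7a, while Hba-a1 and Gata1 had none. Fisher's test counted neighbouring genes as independent in every list, the globin genes among them. How uniquely reads could be placed at the globin genes was not examined. Hepatocyte genes carried Mta2 and Mbd3 at 7 of 18 (adjusted exact p = 0.0392 and 0.0448) and Zbtb7a at 5 (adjusted exact p = 0.00735), with Apoh, Itih1 and Fga but not Ahsg or Cps1. Germ cell genes carried Mta2 and Zbtb7a at 4 of 16 (adjusted exact p = 0.00363 and 0.00501) and Mbd3 at 5 (adjusted exact p = 0.0161). Dazl, Gdf9 and Sycp3 were among them and Acrv1 and Ddx4 were not. Inside their spans Ahsg held 1 Mta2 summit, Cps1 2, Ddx4 2 and Acrv1 0. Striated muscle genes were occupied less often than other genes by Zbtb7a (4 of 15, adjusted exact p = 0.0117) and did not pass for Mta2 (8) or Mbd3 (6), with Mylpf, Ckm and Myh6 but not Actc1 or Myf5. With a −log10 q of at least 10, striated muscle genes also passed as less often occupied for Mta2 (26.7%, in place of 53.3%) and Mbd3 (26.7%, in place of 40.0%), the latter also without olfactory and vomeronasal receptor genes. With summits anywhere in the span, an alternative chosen after seeing the data, the striated muscle call and the hepatocyte calls were lost. Neuron genes did not pass (12, 11 and 9 of 18 for Mta2, Mbd3 and Zbtb7a, with Map2, Syp and Grin1 but not Gad2 or Gria1), nor did zinc finger partners of NuRD (12, 11 and 10 of 15, with Zbtb14, Zfpm1 and, without Zbtb7a at an end, Zbtb7b but not Ikzf1 or Sall1). Gad2 and Gria1 held 2 and 10 Mta2 summits inside their spans, and Ikzf1 and Sall1 5 and 8. With windows of 3 kb the zinc finger partners passed as more often occupied for Mbd3 and Zbtb7a.

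**Figure D4:**
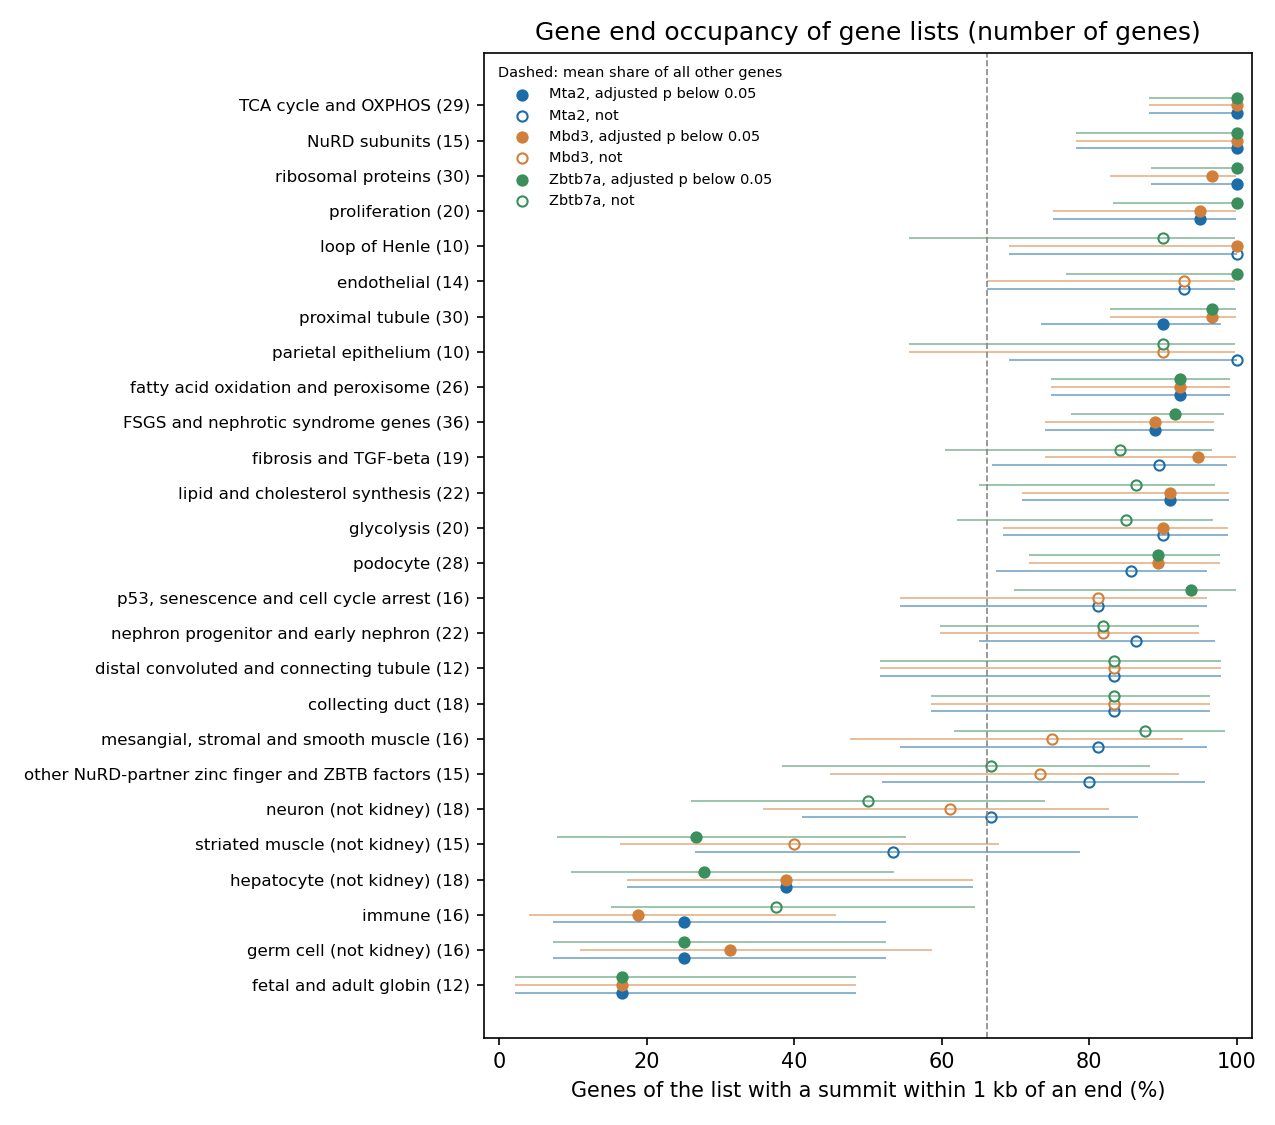
Share of each list's genes with a summit within 1 kb of an end (%), per factor, with exact 95% binomial intervals and the number of genes in brackets; filled points have an adjusted p below 0.05 by Fisher's exact test, and the dashed line is the mean share of all other genes. All 29 TCA cycle and OXPHOS genes carry the factors, against 2 of the 12 genes in the list of globins and their regulators.

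Across the 26 lists, 8 were occupied more often and 4 less often than other genes for Mta2, 12 and 4 for Mbd3 and 10 and 4 for Zbtb7a. A call for one factor and not another does not show that they differ. Of 78 exact McNemar tests between factors within lists, 0 passed adjustment and 0 had an unadjusted p under 0.05, but with at most 4 members that differed in any list the smallest p they could give was 0.125, so they leave such differences open. Without olfactory and vomeronasal receptor genes in the background, the lists occupied more often numbered 3 for Mta2, 8 for Mbd3 and 8 for Zbtb7a, and calls ended for proximal tubule, FSGS, fatty acid oxidation and proliferation genes with Mta2, for podocyte genes with Mbd3 and Zbtb7a, for lipid synthesis genes with Mta2 and Mbd3, for loop of Henle and glycolysis genes with Mbd3 and for p53 genes with Zbtb7a. The loop of Henle call also ended with windows of 0.5 kb and 3 kb, with a −log10 q of at least 10 and with summits anywhere in the span. Lists also gained calls as more often occupied. With windows of 3 kb these were, besides the nephron progenitor genes and zinc finger partners above, podocyte and mesangial genes with Mta2, lipid synthesis and glycolysis genes with Zbtb7a and p53 genes with Mbd3. Equal list lengths gave 5 gained calls and summits anywhere in the span 12, in either direction, which are not named here. With a −log10 q of at least 10 they were loop of Henle, endothelial, glycolysis and fibrosis genes with Mta2 and lipid synthesis genes with Zbtb7a. With 10000 top peaks, fatty acid oxidation was the single list occupied more often, by each factor.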

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

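The test of peak width in the first pattern and the tests of list length and weak peaks in the third were set before their results were seen, and the others in this part after.

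Chromosome Y lay outside the main measurement and carried 143 Mta2 peaks, 156 Mbd3 peaks and 80 Zbtb7a peaks. No comparison above used them.

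The strongest peaks of each factor almost all lay in the other lists too, where any peak past the threshold counts, however weak. Chance does not account for it, since the strongest 10% of Zbtb7a peaks, 99.99% of which overlapped both other lists, reached at most 13.2% over 1000 shifts. The greater width of strong peaks does not account for it either: with every peak reduced to 100 bp on each side of its summit, the strongest 10% still overlapped both others at 93.0% or more, above the 68.4% to 86.6% of the whole lists. Signal that any antibody may collect at open chromatin stays open, since 39.0% of the 500 top Zbtb7a peaks lay in the Mta2 top list, above the 1.4% that shifts reached and below the 69.6% of Mbd3, and no list for an unspecific antibody was used here. Shared recruitment of Zbtb7a and NuRD is a biological explanation that was not tested.

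Of the 500 top Zbtb7a peaks, 276 lay outside the 500 top peaks of both NuRD subunits, and 71.4% of these were near a gene end (95% interval 65.65 to 76.64), against 43.3% of the other 224 (36.7 to 50.1, Fisher's exact p = 2.37e-10). Narrow mapping artefacts are argued against by that 71.4%, since shifts reached at most 7.25%. Higher enrichment of the whole Zbtb7a library would keep the order of its peaks, but its test, the 39.0% of top Zbtb7a peaks in the Mta2 top list against 69.6% for Mbd3, restates the pattern and decides nothing. Of the 276 peaks, 275 overlapped the full Mta2 list and all 276 the full Mbd3 list, where any peak past the threshold counts. Of the strongest 10% of all Zbtb7a peaks, 99.99% overlapped both full lists, so these counts are not particular to the 276. Sequence preference of Zbtb7a and unspecific signal of its antibody were not tested.

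Of 33 muscle and neuron genes, pooled after their shares were seen, 7 carried Mta2 without Zbtb7a and 0 the reverse (exact McNemar p = 0.0156, unadjusted). Other genes leaned the same way, 763 against 419, and the lean of the 33 was not shown to differ from theirs (Fisher's exact p = 0.0565, a test added after these counts were seen). The counts were 4 and 1 with lists of equal length (exact McNemar p = 0.375). With 10000 top peaks they were 0 and 0, with each factor at 2 of the genes (exact McNemar p = 1.0). The excess was then gone, but so few occupied genes could not decide between explanations. Neither the length of the Mta2 list nor weak peaks near the threshold can be told apart from a difference in binding, since fewer than 6 genes were left to decide, a minimum that was set after the counts were seen. No biological explanation was tested.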

How the results depend on the processing

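No paired analysis was possible because 1 peak list stands for both mice of each factor, and for the same reason no mouse could be left out. Equal list lengths, removal of peaks with low fold and high −log10 q, and summits anywhere in a gene's span were chosen after seeing the data. The windows at the 5′ end alone, the background matched on CpG content and all motif results were not run. All 48 alternatives for pairwise overlap stayed above chance, from 61.5% to 94.7% and 8.28 to 69.6 times chance, the lowest multiple with shifts of 50 kb to 1 Mb. All 21 for summits at gene ends did too, from 8.60% to 46.0% and 2.33 to 14.2 times chance. A fold of at least 5 left 78642 Mta2, 67265 Mbd3 and 62354 Zbtb7a peaks, and a −log10 q of at least 10 left 81568 Zbtb7a peaks, by construction. The share of Mta2 peaks in both other lists, 68.4%, became 56.3% with reciprocal overlap, 68.1% with −log10 q of at least 10, 71.3% with 10000 top peaks and 77.4% with equal lengths. Ranked by −log10 q, the weakest 10% in both other lists was 15.5% for Mta2, 27.7% for Mbd3 and 49.1% for Zbtb7a, and the strongest 10% of Mbd3 99.9%. With peaks reduced to 100 bp on each side of the summit, the weakest 10% were 14.0%, 22.7% and 37.2% and the strongest 95.5%, 94.8% and 93.0%. The cause of these shifts was not tested.

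Of 42 calls for gene lists, 39 were lost with 10000 top peaks, which leave fewer occupied genes. The 3 kept were fatty acid oxidation genes for Mta2 (61.5% against 22.5%), Mbd3 (57.7% against 21.9%) and Zbtb7a (53.8% against 24.04%). Lists occupied more often then numbered 1 for each factor and lists less often 0. Under the other alternatives 19 of the 42 were never lost. Lists more often occupied by Mta2 numbered 5 at 0.5 kb, 3 without olfactory and vomeronasal receptor genes and 14 with summits anywhere in the span, and by Mbd3 7 at 0.5 kb. Lists less often occupied numbered 0 for Mta2 at 3 kb and 2 for Zbtb7a with summits anywhere in the span. Changes of direction were counted only where the main or the alternative value passed the test. With 10000 top peaks the direction reversed for podocyte (21.4%) and loop of Henle genes (10.0%) with Mbd3. The same held for endothelial (14.3%) and proliferation genes (15.0%) with Zbtb7a and for ribosomal protein genes with Mta2 (20%). Hepatocyte genes with Mta2 reversed with summits anywhere in the span (77.8%). None of these reversed values passed the test. The cause was not tested.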

Other observations

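The comparisons in this part were chosen after the data were seen. Gene families named by their symbols, with at least 20 members, were compared with all other genes for peaks of all 3 factors at an end, by Fisher's exact test adjusted over all such families. There were 37 families occupied more often and 27 less often. The test counts genes as independent, although members of one family can lie side by side. How uniquely reads could be placed at members of similar sequence was not examined, so missing peaks there cannot be read as missing binding. Of 1110 olfactory receptor genes (Olfr) 10 carried all 3 factors, of 355 vomeronasal receptor genes (Vmn) 3, and of 56 keratin-associated protein genes (Krtap) 0. Defensin genes of the Defa family (0 of 28), prolactin family genes (Prl, 0 of 25), Rhox homeobox genes (0 of 33) and the major urinary protein genes (Mup, 1 of 22, adjusted exact p = 9.64e-08) were alike. Mitochondrial ribosomal protein genes stood at the other side, with 47 of 49 for Mrpl (adjusted exact p = 2.84e-07) and 29 of 29 for Mrps (adjusted exact p = 7.33e-06). Zinc finger genes of the Zfp series carried all 3 at 314 of 397 (79.1%, adjusted exact p = 1.37e-11), solute carriers (Slc) at 281 of 375 (74.9%, adjusted exact p = 1.29e-06), and cytochrome P450 genes (Cyp) at 48 of 99 (48.5%, adjusted exact p = 0.00965), the last below other genes at 62.5%.

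Proximal tubule genes also had many summits around them. Counted over the gene and 50 kb on each side, their median was 23.5 Mta2, 24 Mbd3 and 24 Zbtb7a summits, against 13.0, 11.5 and 11 in 10000 random lists matched on gene length (adjusted p = 0.0104, 0.0078 and 0.0078 over 78 permutation tests, two-sided). Podocyte genes had a median of 21.5 Zbtb7a summits against 12.0, and FSGS genes 20.5 against 12.0 (adjusted p = 0.025 for both, permutation). Zinc finger partners of NuRD had 26.0 Mta2 summits against 14.0 (adjusted p = 0.0468, permutation). No other list passed for any factor.

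A few peaks combined a fold under 3 with a −log10 q above 100. There were 23 in the Mta2 list, 25 in the Mbd3 list and 25 in the Zbtb7a list, of which 16, 17 and 14 lay in the first 4 Mb of chromosome 9. No list of regions prone to artefacts was applied, and whether these peaks are artefacts of repeats was not tested. Without them pairwise overlap was 72.4% to 92.8%. The highest −log10 q of the Mta2 list, 23700.0, belonged to an interval on chromosome 2 (98666584 to 98667293) with a fold of 3.64, and that of Mbd3 to nearly the same interval (98666588 to 98667289, fold 3.46). Ranked by fold in place of −log10 q, 289 of the 500 top Zbtb7a peaks lay outside both NuRD top lists, and 63.0% of these were near a gene end against 28.9% of the rest (Fisher's exact p = 3.5e-14).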
